A study of Mus musculus with 4 samples.

How the data were processed

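Bulk RNA-seq was deposited for cells of the corpus callosum, the main white matter tract of the forebrain, of Mertk-knockout mice given 0.2% cuprizone for 4 weeks. Per the labels' protocols, mice were perfused with PBS, the tissue was dissociated with an enzymatic neural tissue kit, cells were sorted by annexin V staining, and libraries were made from total RNA with the Illumina TruSeq RNA v2 kit, which does not keep strand. Reads from overlapping or antisense genes can therefore not be told apart, also where a gene named below is not marked as overlapping. There were 4 libraries, 2 of AnnexinV-positive and 2 of AnnexinV-negative cells, grouped by the titles. The labels do not say whether the 2 replicates of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical.

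Per the submitters' processing notes, reads were aligned with GSNAP to mm10. The aligner version, the gene counter, the annotation release, the gene lengths and read filters are not given in the sources used here. Each file held 1 value for each of 52636 Ensembl genes under a header that gave no unit. The values were read as RPKM (reads scaled by gene length and depth) that the authors normalized with size factors, from the values themselves: of the values worth under 100 reads, 79.6% to 83.6% per library lay within 0.01 of a whole multiple of a step inversely proportional to the exonic gene length in GENCODE vM21, and the median log2 ratio to the geometric mean of the 4 libraries was 0.03 in each of them over the 34326 genes above 0 in all 4. Of those genes, 69.7% had a mean RPKM under 1, so mostly low-level genes set the deposited scale. Symbols and coordinates came from GENCODE vM21 (GRCm38, the same assembly as mm10), which matched 52403 genes, and lengths were available for 52489.

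The design fixed before the data were examined assumed read counts. Since the deposited values were RPKM, its alternative for such values was used in place of the count test. Values were transformed to log2(RPKM + 0.1), genes with an RPKM of at least 1 in 2 libraries were kept (10927 genes), and limma 3.58.1 in R 4.3.3 with an intensity trend compared AnnexinV-positive minus AnnexinV-negative libraries with no covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 over all genes tested were called changed. Fold changes are on the log2(RPKM + 0.1) scale and understate the change of low genes. An exact permutation test of 2 libraries against 2 has 3 splits and cannot give a p below 0.333, so single values such as library totals are given without a test.

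Fixed lists of genes, 35 in all, were written before the data were examined. They were markers of 14 cell types (mature oligodendrocyte, oligodendrocyte precursor, homeostatic microglia, border macrophage, monocyte, neutrophil, T or NK cell, B cell, astrocyte, neuron, endothelial cell, mural cell or fibroblast, ependymal or choroid plexus cell, erythroid cell) and genes of 21 processes. The 30 lists with at least 3 tested members were tested against all other genes with limma's camera, two-sided, with a preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over lists. Each list also has the number of members past the test over all genes and adjusted over the list alone. None of the 22 list calls held when camera estimated the inter-gene correlation from the residuals. With 2 libraries per group the residuals hold little to estimate it from. Even the mature oligodendrocyte list, with all 15 members lower, had an unadjusted p of 0.0901 in this version of camera. A failure there therefore does not decide against a list call, nor for it.

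Named genes followed a rule fixed before the data were examined: Mertk, Axl, Tyro3, Gas6 and Pros1; the 10 largest changes in each direction among genes past the test with a mean RPKM of at least 1, no overlap between groups and a symbol that is not a clone name; and the 3 members of each list with the smallest p. Other members that had to be named to describe a small count (Asns, Ddit3, Ppp1r15a, Aen, Ccng1, Dock1, Mfge8, Hsph1, Pfkp, Pltp, Cspg4), and Ttr, Cd72, Lag3, Clcf1 and Gm23127 in the closing part, were chosen after their values were seen. So were Gapdh, Pgk1, Rpl18, Rpl4 and Rpl8, which are named for their levels.

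The steps were tested on simulated data for the same comparison and the same 10927 genes, with 200 changed genes. Of 100 genes changed 2-fold, 62% were recovered, and of 100 changed 4-fold, 97%, with 14 false calls and 0 sign errors. A list of 20 genes shifted by 1 log2 unit was called in 20 of 20 runs, in which other lists gave 12 calls. The simulated noise was independent between genes, so the list runs do not cover correlated genes. The 200 changed genes were also far fewer than the 4376 called in the data, so these rates need not hold there.

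Whole reads were recovered by dividing each value by its gene's step. Within 0.01 of a read, 60.7% to 62.3% of the values in a library came out whole, so the reads are approximate. They served for depth, equal-depth and equal-total alternatives, limma-voom, shares of reads, and a comparison of replicates. The replicates were not copies of one library: their recovered reads differed by a chi-square per gene of 23.2 in the AnnexinV-positive and 20.0 in the AnnexinV-negative pair. Alternatives covered each replicate left out, a replicate block, other scalings, other filters and pseudocounts, equal depth, gene length (lowess, span 0.3, lengths for 99.9% of genes tested), limma-voom, a test against a 1.5-fold change, and other list tests. Scaling by equal RPKM totals is called the TPM scale.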

Results

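RNA levels were measured by bulk RNA-seq in sorted cells of the corpus callosum of Mertk-knockout mice after 4 weeks of 0.2% cuprizone, a copper chelator in the diet that kills oligodendrocytes, the myelin-forming cells. Mertk encodes a receptor tyrosine kinase through which phagocytes take up apoptotic cells. Cells were divided by annexin V, a protein that binds phosphatidylserine exposed on dying cells. The series compares dying (AnnexinV-positive) with living (AnnexinV-negative) cells, each with 2 libraries. Reads in genes, recovered from the deposited values and given in units of 1000 reads, were about 67460 and 60147 in AnnexinV-positive libraries 1 and 2, and 50536 and 43254 in AnnexinV-negative libraries 1 and 2. At this depth 1 read in a gene of 1 kb was worth an RPKM of 0.00833 to 0.0116. Between 10208 and 10509 genes per library reached an RPKM of 1. Over the genes tested, Pearson's r of log values was 0.979 within the AnnexinV-positive pair, 0.951 within the AnnexinV-negative pair and 0.821 to 0.865 between libraries of different groups; these are correlations across genes, which are not independent replicates.

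Mertk (chromosome 2, 128698956 to 128802894, plus strand, GRCm38, protein coding) was read in every library, at an RPKM of 62.6 and 53.6 in the AnnexinV-positive and 18.8 and 29.9 in the AnnexinV-negative libraries. All 4 libraries carry the knockout label, there is no wild-type library, and a value for the whole gene does not separate deleted from remaining exons, so these levels do not check the genotype.

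AnnexinV-positive libraries held far less RNA of oligodendrocytes: all 15 markers of mature oligodendrocytes were lower, by a median of -4.74 on the log2 scale, and all 15 also on the centred and TPM scales. All 14 markers of homeostatic microglia, the resident macrophages of the brain, were higher on the deposited scale, by a median of 1.196, but 11 passed on the centred scale and 0 on the TPM scale, where the median was 0.42. Markers of oligodendrocyte precursors (8 of 9 tested), astrocytes (9 of 11), neurons (2 of 3), endothelial cells (7 of 9) and mural cells or fibroblasts (3 of 5) fell as well. Of 12 listed neuron markers only 3 reached the RPKM minimum, and of 12 mural or fibroblast markers 5. The precursor marker Pdgfra did not reach it. On the deposited scale, genes of disease-associated microglia (19 of 20), inflammatory cytokines (14 of 15), MHC class I (11 of 11) and MHC class II presentation (4 of 6) rose, and of these lists MHC class II did not pass camera. On the TPM scale 5, 6, 0 and 2 of these members were higher, in the same order. With each library centred on the homeostatic microglia list, 1, 0, 0 and 0 were higher. No list call held with an estimated correlation (camera adjusted p = 0.342 with an estimated correlation at the lowest), for which 2 libraries per group leave little data. The preset correlation treats members as nearly independent, so neither version of camera settles the list calls. In all, 4376 of 10927 genes changed (limma, Benjamini-Hochberg adjusted p under 0.05), 3364 higher and 1012 lower in AnnexinV-positive cells, of which 1509 and 881 differed at least 2-fold.

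The direction of small changes depended on the scale. The median log2 fold change of the genes tested was 0.45 on the deposited scale, and with each library centred on the median of these genes 713 were higher and 1303 lower, against 114 and 2104 on the TPM scale and 219 and 1697 with total reads made equal. A single library also moved the counts: without AnnexinV-positive replicate 1 or 2, 1749 and 1297 genes were higher, and without AnnexinV-negative replicate 1 or 2, 329 and 432 were lower when the genes tested were chosen again, but 897 and 1060 when they were held. The groups did not overlap for 75.9% of genes, where chance gives 33.3% for a single gene in 2 libraries against 2. The share was taken on the deposited scale, where the genes tested were shifted together, and genes are not independent. The difference between these shares is therefore not a test.

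**Figure D1:**
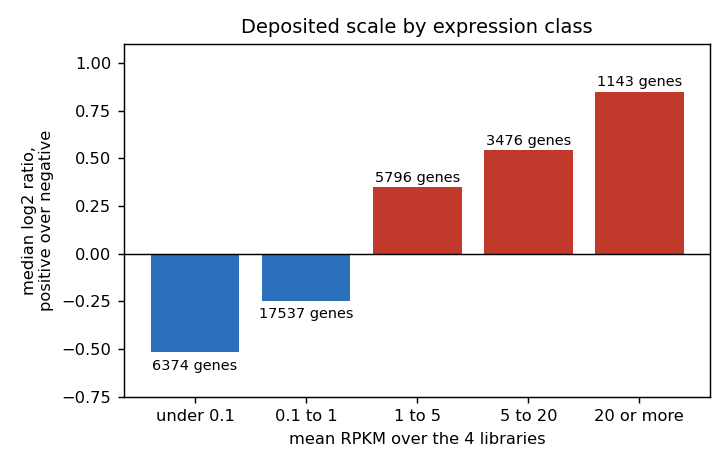
Median log2 ratio of AnnexinV-positive over AnnexinV-negative libraries on the deposited scale (vertical axis) for genes above 0 in all 4 libraries, in classes of mean RPKM (horizontal axis). The median was -0.52 for the 6374 genes under an RPKM of 0.1 and 0.85 for the 1143 genes at 20 or more.

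The mature oligodendrocyte list fell in all 15 of its members, also when adjusted over the list alone (15 lower), on the centred scale (15 lower) and on the TPM scale (15 lower). Its camera test gave an adjusted p of 1.58e-23 (limma), and adjusted p = 0.342 with an estimated correlation. Mog, a protein of the outer myelin surface (chromosome 17, 37010743 to 37023398), was at an RPKM of 0.185 ± 0.0492 (SD, n = 2) in AnnexinV-positive and 21.0 ± 11.4 (SD, n = 2) in AnnexinV-negative cells, a log2 fold change of -6.11 (SE 0.38, limma adjusted p 2.70e-04). Mobp, another myelin protein, fell by 6.01 and Ermn, a cytoskeletal protein of oligodendrocytes, by 5.28 on the log2 scale. Of 9 tested members of the oligodendrocyte precursor list, 8 fell (8 adjusted over the list alone, 8 on the centred and 8 on the TPM scale), with a median of -1.79 (camera adjusted p 8.68e-09, limma; adjusted p = 0.342 with an estimated correlation). The transcription factors Olig2 and Olig1, which oligodendrocytes of all stages express, had log2 fold changes of -4.81 and -4.54, and Bcas1 of -4.19. Cspg4 was the tested member that did not pass, at 0.55 (limma adjusted p 0.237). Pdgfra, Tnr and Matn4 did not reach the RPKM minimum and were not tested.

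The 10 largest decreases under the naming rule were Pex5l (-6.60), Gjb1 (-6.59), Efnb3 (-6.39), Mog (-6.11), Dusp26 (-6.05), Mobp (-6.01), Nkx6-2 (-6.004), Gjc3 (-5.90), Stmn4 (-5.84) and Apod (-5.81), as log2 fold changes. Gjb1 and Gjc3 encode gap junction proteins of oligodendrocytes, and Nkx6-2 a transcription factor of that lineage. Pex5l, Mobp and Nkx6-2 share exon bases with other genes. Pex5l (chromosome 3, 32949408 to 33143247) went from an RPKM of 20.1 ± 2.15 to 0.111 ± 0.0516 (SD, n = 2 each). Apod, a secreted lipid-binding protein, went from 68.1 ± 34.5 to 1.06 ± 0.306 (SD, n = 2 each).

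Astrocyte markers fell by less: 9 of 11 were lower (9 adjusted over the list alone, 10 centred, 11 on the TPM scale), with a median of -1.27 (camera adjusted p 9.07e-09, limma; adjusted p = 0.342 with an estimated correlation). The list did not pass limma's fry test (adjusted p 0.104). Among its members, the gap junction genes Gja1 and Gjb6 had log2 fold changes of -1.73 and -1.39, and the growth factor receptor Fgfr3 of -1.53. Endothelial markers fell in 7 of 9 members (7 adjusted over the list alone; 7 centred, 8 on the TPM scale), with a median of -2.63 (camera adjusted p 2.44e-09, limma; adjusted p = 0.342 with an estimated correlation), including the tight junction gene Cldn5 (-2.90), Esam (-2.86) and Slco1a4 (-2.66). Mural and fibroblast markers fell in 3 of 5 members (5 adjusted over the list alone; 3 centred, 5 on the TPM scale), Pdgfrb (-3.12), Kcnj8 (-3.09) and Rgs5 (-3.00), all known from pericytes (camera adjusted p 3.52e-06, limma; adjusted p = 0.342 with an estimated correlation). Neuron markers fell in 2 of 3 tested members, Tubb3 (-4.68) and Stmn2 (-3.58), while Snap25 was at -0.62 with a limma adjusted p of 0.0750. Adjusted over the list alone 3 were lower, with 3 centred and 3 on the TPM scale (camera adjusted p 1.42e-04, and adjusted p = 0.342 with an estimated correlation). The list has 12 members, of which Rbfox3, Syt1, Nefl, Nefm, Gad1, Gad2, Slc17a7, Camk2a and Nrgn did not reach the RPKM minimum. The tested members therefore say little about RNA of neurons. The ependymal or choroid plexus list had no member past the test over all genes or adjusted over the list alone, among 6 tested, and its median of 0.57 turned to -0.13 on the TPM scale (camera adjusted p 0.521, limma, downward). Its members Kcnj13 (6.14 ± 5.09 against 5.003 ± 5.42 RPKM) and Folr1 (2.94 ± 2.40 against 2.25 ± 2.44 RPKM, SD, n = 2) varied more within than between groups, and Rsph1 had a log2 fold change of 0.54 (SE 0.68).

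**Figure D2:**
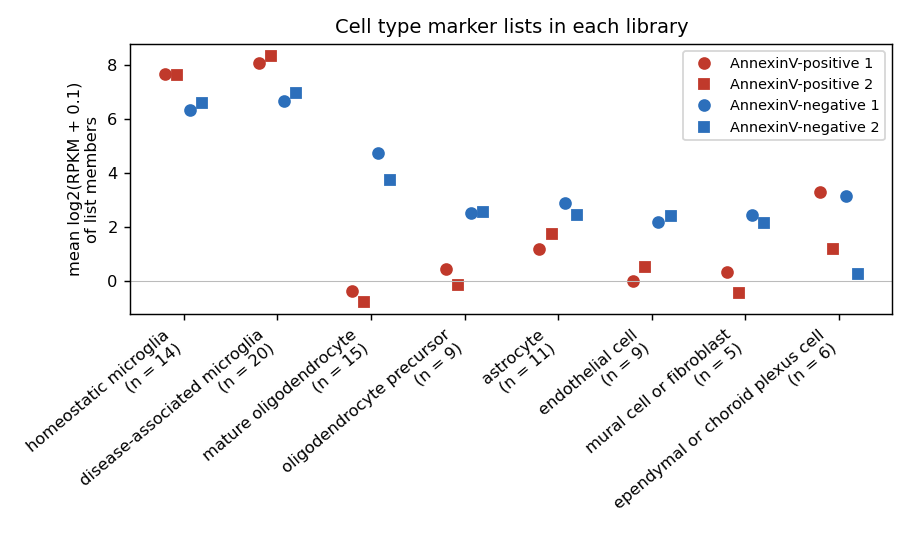
Mean log2(RPKM + 0.1) of the tested members of 8 fixed lists (vertical axis) in each of the 4 libraries (red, AnnexinV-positive; blue, AnnexinV-negative; circles and squares, replicates 1 and 2). Both AnnexinV-positive libraries lie above both AnnexinV-negative libraries for the microglial lists and below them for the oligodendrocyte, astrocyte and vascular lists, while the ependymal or choroid plexus list differs between replicates.

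Homeostatic microglia markers rose in all 14 members (14 adjusted over the list alone; 11 on the centred scale, 0 past the test on the TPM scale), with a camera adjusted p of 1.42e-04 (limma) and adjusted p = 0.342 with an estimated correlation. Siglech, a lectin of microglia, went from an RPKM of 31.0 ± 0.0498 to 74.6 ± 0.561, Selplg from 157 ± 14.2 to 395 ± 14.6, and Sparc from 204 ± 11.6 to 492 ± 47.5 (SD, n = 2 each). All 3 tested markers of border macrophages rose: Ms4a7 (1.57), Pf4 (1.19) and Folr2 (1.15 on the log2 scale). Adjusted over the list alone 3 passed, with 1 centred and 0 on the TPM scale, and the list did not pass camera (adjusted p 0.0917, limma). Centred on the microglia list, the median was 0.01 with 0 past the test. The list has 10 members, of which Mrc1, Lyve1, Cd163, F13a1, Cbr2, Cd209f and Clec10a did not reach the RPKM minimum. The 3 rises therefore do not show more RNA of border macrophages. Fn1, the tested member of the monocyte list, was at 0.56 (limma adjusted p 0.353; 0 of 1 past the test over all genes or adjusted over the list alone) and at -0.21 on the TPM scale. Of 3 tested neutrophil markers, the calcium-binding proteins S100a9 (-4.54) and S100a8 (-4.52) fell and the cytokine receptor Csf3r, which microglia also express, rose by 1.19 (1 higher and 2 lower adjusted over the list alone; 0 and 2 centred, 0 and 2 on the TPM scale; camera adjusted p 0.0247, limma; adjusted p = 0.342 with an estimated correlation). Gzmb, a protease of cytotoxic lymphocytes, fell by 1.82, and Nkg7 was at -0.90 with a limma adjusted p of 0.324 (1 of 2 members lower, also adjusted over the list alone, centred and on the TPM scale). Both tested B cell markers rose, Cd79b by 1.46 and Ighm by 1.17 (2 adjusted over the list alone; 2 centred, 0 on the TPM scale, and 0 with a median of 0.14 centred on the microglia list). The erythroid list had 1 tested member, Hbb-bs, at -0.74 (limma adjusted p 0.277; 0 adjusted over the list alone), which shares reads with near-identical globin genes. The nucleus-retained RNAs Malat1 and Neat1 were at -0.48 and -0.25, with 0 of 2 past the test over all genes or adjusted over the list alone, and 1 lower on the centred and 1 on the TPM scale.

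Disease-associated microglia genes, which microglia raise around damaged myelin and plaques, rose in 19 of 20 members (19 adjusted over the list alone; 15 centred, 5 on the TPM scale), with a median of 1.37, or 0.19 with 1 past the test centred on the microglia list. The disease-associated list had a camera adjusted p of 1.61e-05 (limma; adjusted p = 0.367 with an estimated correlation). The integrin Itgax (chromosome 7, 128129547 to 128150657) rose by 2.17 (SE 0.23, limma adjusted p 0.00138), from an RPKM of 8.14 ± 1.60 to 36.9 ± 7.29 (SD, n = 2 each). The galectin Lgals3 rose by 1.78 and the lectin Clec7a by 1.39. Inflammatory cytokines and NF-kB targets rose in 14 of 15 members (15 adjusted over the list alone; 12 centred, 6 on the TPM scale), with a median of 1.44, or 0.26 with 0 past the test centred on the microglia list. The inflammatory list had a camera adjusted p of 6.27e-05 (limma; adjusted p = 0.342 with an estimated correlation). Among these, Cxcl2, a chemokine for neutrophils, rose by 1.72, and the cytokines Il1b and Tnf by 1.58 each on the log2 scale. The homeostatic microglia list rose by a median of 1.196 in the same libraries.

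The 10 largest increases under the naming rule were Ccl7 (3.16), Mir1903 (2.63), Mmp12 (2.56), Postn (2.21), Klk8 (2.20), Itgax (2.17), Batf3 (2.13), Srxn1 (1.99), Olr1 (1.92) and Tnfaip2 (1.87), as log2 fold changes. Ccl7, a chemokine for monocytes (chromosome 11, 82045712 to 82047525), went from an RPKM of 0.317 ± 0.139 to 3.61 ± 1.09, and Mmp12, an elastase of macrophages, from 1.16 ± 0.166 to 7.43 ± 1.86 (SD, n = 2 each). Mir1903 overlaps an exon of Nrp1 and is uncertain, since reads of the pair cannot be told apart. Mmp12, Klk8 and Tnfaip2 also share exon bases with another gene (Mmp1b, 2310002F09Rik and Gm40578).

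Antigen presentation and interferon genes rose too. All 11 genes of MHC class I presentation were higher (11 adjusted over the list alone; 8 centred, 0 on the TPM scale), with a median of 1.33, or 0.15 with 0 past the test centred on the microglia list. The class I list had a camera adjusted p of 5.38e-04 (limma; adjusted p = 0.342 with an estimated correlation). H2-Q7, H2-K1 and H2-D1 rose by 1.39, 1.34 and 1.33, but are near-identical copies whose shared reads make the single values uncertain. In the MHC class II list 4 of 6 members rose (4 adjusted over the list alone; 3 centred, 2 on the TPM scale), among them Cd74 (1.69), H2-DMb1 (1.46) and H2-DMa (1.24), and the list did not pass camera (adjusted p 0.0917, limma). Type I interferon response genes rose in 18 of 20 members (19 adjusted over the list alone; 6 centred, 1 on the TPM scale), with a median of 1.03. The interferon list had a camera adjusted p of 2.15e-04 (limma; adjusted p = 0.342 with an estimated correlation). The chemokine Cxcl10 (1.64), the ubiquitin-like Isg15 (1.43) and Oas1a (1.19) were the named members. With libraries centred on the homeostatic microglia list, the medians of the interferon and MHC class II lists turned to -0.14 and -0.12.

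**Figure D3:**
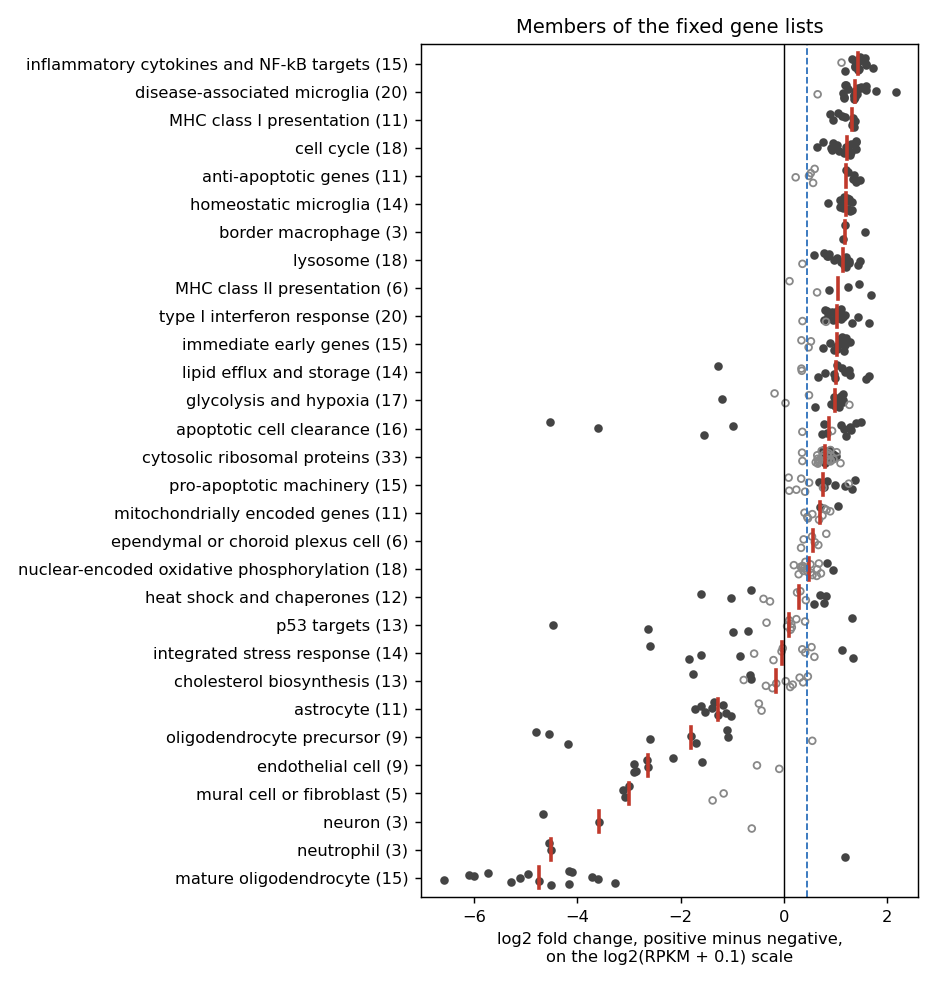
Log2 fold changes (horizontal axis, AnnexinV-positive minus AnnexinV-negative) of the tested members of the 30 fixed lists with at least 3 tested members (vertical axis, number tested in brackets). Filled points passed the test over all genes, open points did not, red bars are list medians and the dashed line is the median of the genes tested, 0.45; medians run from -4.74 for mature oligodendrocytes to 1.44 for inflammatory genes.

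Genes of cell death moved in part. Pro-apoptotic genes rose in 7 of 15 members (8 adjusted over the list alone; 2 centred, 0 on the TPM scale), with a median of 0.76 that turned to -0.42, with 4 members lower, when libraries were centred on the microglia list. The pro-apoptotic list had a camera adjusted p of 0.0889 (limma). Casp8, an initiator caspase, rose by 1.38, Pmaip1, a BH3-only protein, by 1.31, and Bid by 0.99. Anti-apoptotic genes rose in 6 of 11 members (6 adjusted over the list alone; 5 centred, 1 on the TPM scale), with a median of 1.197, or 0.02 with 3 lower centred on the microglia list. The anti-apoptotic list had a camera adjusted p of 0.0125 (limma; adjusted p = 0.342 with an estimated correlation). Bcl2a1b (1.48), Bcl2a1a (1.39) and Bcl2a1d (1.34) were the named members, and are near-identical copies with uncertain single values. Of 13 tested p53 targets, Pmaip1 rose, while Phlda3 (-4.47), Eda2r (-2.64), Aen (-0.99) and Ccng1 (-0.69) fell (1 higher and 4 lower adjusted over the list alone; 1 and 4 centred, 0 and 5 on the TPM scale). The median of the p53 list was 0.10, its mean -0.51 and its median on the centred scale -0.32, with camera downward (adjusted p 0.00850, limma; adjusted p = 0.342 with an estimated correlation). In the integrated stress response list, Atf3 (1.34) and Ppp1r15a (1.13) rose and Trib3 (-2.60), Asns (-1.83), Ddit4 (-1.60) and Ddit3 (-0.85) fell, among 14 tested (3 higher and 4 lower adjusted over the list alone; 2 and 5 centred, 0 and 8 on the TPM scale). Its median was -0.03 and camera was downward (adjusted p 0.0277, limma; adjusted p = 0.342 with an estimated correlation; fry adjusted p 0.655). The oligodendrocyte, astrocyte and vascular lists fell in the same libraries, by medians of -4.74, -1.27 and -2.63.

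Heat shock genes went both ways, with 4 higher and 3 lower of 12 (4 and 3 adjusted over the list alone; 0 and 3 centred, 0 and 5 on the TPM scale). Dnajb1 rose by 0.77, a change that turned to -0.0057 on the TPM scale, and Hspb1 (-1.61), Hspa1b (-1.02, near-identical to Hspa1a and uncertain) and Hsph1 (-0.65) fell. The list's median was 0.29, its mean -0.01 and its centred median -0.14, with camera downward (adjusted p 0.185, limma). Immediate early genes, which cells switch on within minutes of a stimulus, rose in 12 of 15 members (14 adjusted over the list alone; 7 centred, 0 on the TPM scale), with a median of 1.03 that turned to -0.14 centred on the microglia list. Immediate early genes together had a camera adjusted p of 8.00e-04 (limma; adjusted p = 0.390 with an estimated correlation). Junb (1.28), Nr4a1 (1.196) and Btg2 (1.17) were the named members. All 18 cell cycle genes rose (18 adjusted over the list alone; 8 centred, 0 on the TPM scale), with a median of 1.23, or 0.05 with 0 past the test centred on the microglia list. The cell cycle list had a camera adjusted p of 1.42e-04 (limma; adjusted p = 0.342 with an estimated correlation). The mitotic kinases Cdk1 and Aurkb rose by 1.40 and 1.26, and the cyclin Ccna2 by 1.30.

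Receptors and bridging molecules for apoptotic cells split. Of 16 tested genes of apoptotic cell clearance, 10 rose and 4 fell (11 and 4 adjusted over the list alone; 2 and 4 centred, 0 and 4 on the TPM scale). Axl, a receptor related to Mertk, rose by 1.49 (SE 0.26, limma adjusted p 0.00615), from an RPKM of 48.7 ± 16.0 to 133 ± 14.1, and Mertk itself by 1.28 (SE 0.25, limma adjusted p 0.00920), from 24.4 ± 7.86 to 58.1 ± 6.34 (SD, n = 2 each). Centred on the microglia list, Axl was at 0.31 and Mertk at 0.11 (limma adjusted p 0.265 and 0.689). Their ligands Pros1 and Gas6 rose by 1.11 and 0.83 (limma adjusted p 0.0105 and 0.0480), changes that turned to -0.065 and -0.35 centred on the microglia list. Tyro3, the remaining receptor of the family, fell by 4.53 (limma adjusted p 7.67e-04), and Megf10, a phagocytic receptor of astrocytes, by 3.61. Dock1 (-1.55) and the bridging protein Mfge8 (-0.98) fell too. The mature oligodendrocyte and astrocyte lists fell in the same libraries, by medians of -4.74 and -1.27. The falls of these clearance genes cannot be told apart from a different mix of cells. The list's median was 0.88 and its mean 0.12, the median turned to -0.30 centred on the microglia list, and camera was downward (adjusted p 0.962, limma).

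Lipid handling genes rose in 11 of 14 members and Pltp, a phospholipid transfer protein, fell by 1.28 (11 and 1 adjusted over the list alone; 5 and 1 centred, 2 and 1 on the TPM scale). The list had a median of 1.01, -0.17 centred on the microglia list (camera adjusted p 0.0247, limma; adjusted p = 0.342 with an estimated correlation). The apolipoproteins Apoc1 and Apoe rose by 1.65 and 1.59, Apoe from an RPKM of 3229 ± 8.65 to 9750 ± 734 (SD, n = 2 each), and the lysosomal cholesterol carrier Npc2 by 1.27. Cholesterol biosynthesis genes fell in 3 of 13 members, Sqle (-1.75), Sc5d (-0.65) and Msmo1 (-0.63), with 1 lower adjusted over the list alone, 4 on the centred and 6 on the TPM scale. In the same libraries the mature oligodendrocyte and astrocyte lists fell by medians of -4.74 and -1.27. Sc5d did not pass without any 1 of the 4 libraries, nor Msmo1 without either AnnexinV-positive replicate or AnnexinV-negative replicate 1. Their median was -0.15 (camera adjusted p 0.00632, limma; adjusted p = 0.342 with an estimated correlation; fry adjusted p 0.113). Lysosome genes rose in 17 of 18 members (17 adjusted over the list alone; 5 centred, 1 on the TPM scale), with a median of 1.14, or -0.04 centred on the microglia list. The lysosome list had a camera adjusted p of 3.70e-04 (limma; adjusted p = 0.407 with an estimated correlation). The protease Ctss rose by 1.48, and Cd68 and Hexa by 1.27 and 1.204.

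Glycolysis and hypoxia genes rose in 12 of 17 members and Pfkp, a phosphofructokinase, fell by 1.19 (14 and 1 adjusted over the list alone; 3 and 1 centred, 0 and 2 on the TPM scale), with a median of 0.996, or -0.18 centred on the microglia list. The glycolysis list had a camera adjusted p of 0.0379 (limma; adjusted p = 0.342 with an estimated correlation). Tpi1 (1.14), Aldoa (1.06) and Eno1 (0.996) were the named members. Gapdh and Pgk1 were at a mean RPKM of 1.28 and 3.45 in AnnexinV-positive libraries, against 268 for Aldoa. Whether such low values reflect the RNA of these genes was not tested, so their single values are uncertain. Cytosolic ribosomal protein genes rose in 13 of 33 members (21 adjusted over the list alone; 0 centred, 0 on the TPM scale), with a median of 0.80, or -0.38 centred on the microglia list (camera adjusted p 0.0125, limma; adjusted p = 0.715 with an estimated correlation; fry adjusted p 0.189), among them Rplp0 (0.95), Rpl6 (0.94) and Rps9 (0.88). Levels within the ribosomal list differed widely. In AnnexinV-positive libraries the mean RPKM was 1.56 for Rpl18 and 3.28 for Rpl6, against 116 for Rpl4 and 117 for Rpl8. Whether the low values reflect the RNA of these genes was not tested, so the counts and the camera call of this list are uncertain. Nuclear-encoded oxidative phosphorylation genes rose in 2 of 18 members, Ndufa1 (0.94) and Uqcrb (0.83), with 0 adjusted over the list alone, and Cox4i1 was at 0.72 (limma adjusted p 0.0666). Their median of 0.48 turned to -0.29 on the TPM scale (camera adjusted p 0.521, limma). Of 11 mitochondrially encoded genes, mt-Nd6 (1.05) and mt-Nd5 (0.71, -0.07 on the TPM scale) rose and 0 passed adjusted over the list alone, while mt-Nd1 was at 0.90 (limma adjusted p 0.0527). Their median of 0.71 turned to -0.07 on the TPM scale (camera adjusted p 0.388, limma).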

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

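The runs centred on the genes tested or on the microglia list, the TPM scale, the RPKM minimum of 5, the crossed pairing and the choice to hold the genes tested when a replicate was left out were chosen after the data were seen; the others were fixed before the data were examined. Leaving out a replicate leaves 1 library in a group, which is assumed to vary like the other group. Over these runs, with the genes tested held or chosen again, 1297 to 3356 genes were higher and 329 to 1060 lower; without AnnexinV-positive replicate 1 or 2, 1749 and 1297 were higher with the genes held, and 1926 and 1451 with the genes chosen again. With the genes chosen again the lower counts were 329 and 432 without AnnexinV-negative replicate 1 or 2, since genes read mainly in AnnexinV-negative cells then fail the minimum; this version was run first, and with the genes held these counts were 897 and 1060. Of the 106 named calls, 94 to 103 were kept without 1 replicate with the genes held; those lost in at least 1 run were Sc5d, Msmo1, mt-Nd5, mt-Nd6, Gas6, Uqcrb, Ndufa1, Rpl6, Rplp0, Rps9, Dnajb1, Hspa1b and Folr2. Scaling moved the counts most among the choices tried: 219 higher and 1697 lower with total reads equal, 114 and 2104 on the TPM scale, 713 higher centred on the median, 690 higher with median-of-ratios scaling over the genes tested, and 13 and 5535 centred on the microglia list, because each shifts all genes of a library together. Of the named calls, 89 were kept centred on the median, 68 with total reads equal, 60 on the TPM scale (2 of opposite sign), 48 centred on the microglia list (17 of opposite sign) and 69 against a 1.5-fold change. Of the 4376 calls, 1725 were shared on the centred scale, with 0 in the opposite direction. Without a filter 1865 genes were higher and 2489 lower, with more genes tested (44826). With an RPKM minimum of 5, 270 genes and 6 lists were lower, with fewer genes tested (5028). Against a 1.5-fold change 306 and 606 passed. With an estimated inter-gene correlation, for which 2 libraries per group leave little data, 0 lists were higher and 0 lower. With fry, which does not compare a list with other genes, 13 lists were higher and 7 lower; astrocyte, cholesterol biosynthesis, ribosomal protein and integrated stress response lists lost their call, and border macrophage and pro-apoptotic lists gained one. With a replicate block 2443 genes were higher and 957 lower, the same-numbered deviations correlated at -0.21, and of the named calls 103 were kept, Sc5d, Msmo1 and Uqcrb being lost. The crossed pairing gave 4891 and 1136. Pseudocounts of 1 and 0.01, equal depth, the length trend removed and limma-voom (3677 and 1067) kept the counts within 1.5 times.

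On the TPM scale mt-Nd5 turned to -0.071 and Dnajb1 to -0.0057. Centred on the microglia list, the log2 fold changes turned to -0.47 for mt-Nd5, -0.41 for Dnajb1, -0.35 for Gas6, -0.34 for Uqcrb, -0.29 for Rps9, -0.24 for Rpl6, -0.23 for Ndufa1, -0.23 for Rplp0, -0.19 for Bid, -0.18 for Eno1, -0.13 for mt-Nd6, -0.12 for Aldoa, -0.065 for Pros1, -0.034 for Tpi1, -0.023 for Folr2, -0.0093 for Ighm and -0.0044 for Btg2, by construction where a gene rose by less than the microglial markers. The medians of the ependymal or choroid plexus and apoptotic cell clearance lists turned to -0.61 and -0.30. Without 1 replicate the latter ranged from 0.52 to 1.29, and its camera direction turned upward without AnnexinV-negative replicate 2 and the genes chosen again; the cause was not tested. The planned count-model tests were not run, since the values are not counts, nor was the removal of mitochondrial and the most abundant genes before normalization, since the deposited values carry a fixed scale. With 62% of 2-fold changes recovered in simulated data with 200 changed genes, smaller changes can be missed with 2 libraries per group, though this rate need not hold for these data.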

Other observations

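The tests in this part were chosen after the result was seen, except the thinning to equal depth and the share of 7 lists past the test after centring on the microglia list. The bounds for that share were written before its result, but the centring it rests on was chosen after the data were seen. With each library centred on the homeostatic microglia list, 13 genes were higher in AnnexinV-positive cells: Ccl7 (1.99), Gm23127, Mmp12 (1.38), Postn (1.03), Klk8 (1.02), Itgax (0.99), Batf3 (0.96), Srxn1 (0.81), Olr1 (0.75), Tnfaip2 (0.70), Cd72 (0.67), Lag3 (0.67) and Clcf1 (0.64), as log2 fold changes. Lag3 is a receptor that binds MHC class II, and Clcf1 a cytokine of the IL-6 family. Gm23127 overlaps an exon of Ell2 and is uncertain. Mmp12, Klk8, Tnfaip2 and Cd72 share exon bases with another gene too (Tesk1 for Cd72). Ttr, the main secreted protein of the choroid plexus, was at an RPKM of 383 and 54.2 in AnnexinV-positive libraries 1 and 2, and 360 and 18.4 in AnnexinV-negative libraries 1 and 2. The ependymal or choroid plexus list, which holds Ttr, was likewise higher in replicate 1 of both groups. Its mean log2(RPKM + 0.1) was 3.31 and 1.21 in AnnexinV-positive, and 3.14 and 0.26 in AnnexinV-negative libraries. Mitochondrially encoded genes went opposite ways in the 2 groups, at 4.92 and 5.33 against 4.97 and 3.91. Same-numbered deviations correlated at -0.21. Whether same-numbered libraries shared a dissection therefore stays open.

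Genes tested were on the whole higher in AnnexinV-positive libraries on the deposited scale. Unequal depth does not account for this, since the median stayed at 0.42 after every library was thinned to the smallest total and the size factors were computed again. Chemoreceptor genes, which brain cells hardly express, took 1.57 times as large a share of the reads in AnnexinV-negative as in AnnexinV-positive libraries (0.163% and 0.164% against 0.116% and 0.0918%). The size factors may therefore have been fitted to low-level reads that made up more of the AnnexinV-negative libraries. No biological explanation was tested.

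Oligodendrocyte genes were lower in AnnexinV-positive libraries. A larger share of microglia that diluted every other cell type alike would lower oligodendrocyte and astrocyte markers equally, but the mature oligodendrocyte median lay at -3.47 relative to the astrocyte median, and the middle ranges of both lists (-5.50 to -4.14 and -1.46 to -1.07) did not overlap. Loss of RNA from dying oligodendrocytes that were sorted as AnnexinV-positive might also lower these genes. The median marker was left at 2.30% of its AnnexinV-negative level, but without numbers of sorted cells per type this loss cannot be told apart from fewer oligodendrocytes in the gate. A difference in which cells bound annexin V, which the design names, stays open and untested.

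Genes of several lists rose by about as much as the homeostatic markers, though bulk RNA does not show which cells expressed them. Of 114 tested members of 7 lists (disease-associated, inflammatory, interferon, MHC class I, lysosome, cell cycle and immediate early), 6 passed after centring on the microglia list, 1 higher and 5 lower. This 5.26% lies between the bounds set for dilution alone and against it. Small shifts of single genes can be missed with 2 libraries per group, so dilution by other cell types cannot be told apart from changes within microglia. Centred on the microglia list, the medians were 0.19 (disease-associated), 0.26 (inflammatory), 0.15 (MHC class I), 0.05 (cell cycle), -0.04 (lysosome), -0.14 (interferon) and -0.14 (immediate early). A stronger dissociation stress response in AnnexinV-positive cells stays open too: the centred median of the immediate early list (-0.14) lay within the SD of its members (0.29), while that of the heat shock list (-0.89) lay below 0 by more than its SD (0.781), which goes against it, though the median of all genes fell to -0.73 under the same centring. No value separates these explanations from a different state of AnnexinV-positive microglia, which was not tested.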
